A study of Mus musculus with 99 samples.

How the data were processed

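RNA sequencing was used to measure gene expression in 4 brain regions of mice after chronic social defeat stress, a procedure in which mice meet an aggressor repeatedly and are then classed by their behaviour as susceptible or resilient. Each region had 7 conditions: control, resilient and susceptible mice given saline, and susceptible mice given ketamine or imipramine, as responders or non-responders. Tissue from 2 mice was pooled for each library per the labels, RNA was extracted with TRIzol, and poly-A-selected libraries that do not mark the strand were read as 50 bp pairs. The labels do not say whether the 4 regions came from the same mice, or when a library was prepared or sequenced.

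The authors deposited one table of raw read counts per Ensembl gene, with no normalization, for 37991 genes and all 99 libraries, in whole numbers. Per the submitters' processing notes, the tools were Bowtie2 2.1.0, TopHat2 2.0.9 and HTSeq 0.6.0 on genome build NCBIM37; the counting settings and the annotation release are not stated. Columns were joined to samples by the sample numbers in the titles. Gene symbols were found for 32919 of the IDs (86.6%) by exact ID in a mouse annotation of a later build, so no coordinates are given. Total counts per library ranged from 14459028 to 59187954. Among 132 pairs of libraries of the same group, 0 were identical, and the lowest chi-square per degree of freedom between any pair was 4.632. Precision was therefore set by the spread between libraries, and each difference is given with the standard error from the fit.

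Differential expression was fitted in R 4.3.3 with edgeR 4.0.16, 1 fit per region with a mean for each of the 7 groups and no covariate. Genes were kept with filterByExpr (minimum count 10), library sizes were scaled with TMM, and groups were compared with the quasi-likelihood F-test with robust dispersion. p-values were adjusted over the genes tested in that region with the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. The number of genes at an unadjusted p below 0.05 is given beside each count, with the number that chance would give and the number that also differed by at least 1.3-fold. The 9 comparisons were susceptible with control, resilient with control, resilient with susceptible, each of the 4 drug groups with susceptible saline, and responders with non-responders for each drug. Whether a difference itself varied between regions was tested with an F-test in a fit of all 99 libraries.

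Gene lists were tested with camera in limma 3.58.1 on log2 CPM (counts scaled to library size, prior count 2) with a preset correlation between genes of 0.01, with adjustment over 30 lists, 9 comparisons and 4 regions. The same test with an estimated correlation and the rotation test fry were run beside it. Members called by edgeR were counted over all genes and adjusted over the list alone. For lists discussed at length, the difference between group means of the list's mean log2 CPM was also tested by relabelling libraries, two-sided and exact. With 3 libraries against 3, that p cannot go below 0.1. There were 16 lists of processes and gene families and 14 of markers of cell types or neighbouring tissue.

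To ask whether drug responders moved against or along the stress difference, differences that share no library were correlated across genes (Pearson r), 5 pairs of comparisons in each region. Both sets of labels were permuted together, two-sided, and the 20 p-values were adjusted. Comparisons that share the susceptible saline libraries are given only beside the correlation and covariance simulated for unchanged groups, because 3 libraries cannot be divided into parts of at least 2.

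Groups, comparisons, lists, tests and the rule for named genes were fixed before the data were examined. Under that rule, the genes named per comparison and region were the 4 called genes with the largest log2 fold change in each direction at an average log2 CPM of at least 1, leaving out clone-like symbols. Up to 3 members with the smallest p were added from each list that passed or held called genes. Where no gene was called, the gene with the smallest p in each direction was named as not past the test. Fos, Arc, Egr1, Bdnf, Fkbp5, Sgk1, Crh and Ttr were always given for susceptible against control mice, and up to 5 genes per region could be named for a correlation. Genes named outside the rule are marked as chosen after their values were seen.

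Alternatives fixed in advance were median-ratio scaling in place of TMM, no filter on low counts, DESeq2 1.42.0 in place of edgeR, the 5 consecutive series into which the sample numbers fall as a covariate, leaving out each library of the compared groups in turn, an estimated correlation for the lists, and, for the correlations, Spearman's rho and genes with an average log2 CPM of at least 3. A pair of further alternatives was chosen after seeing the data: leaving out 1 imipramine responder library that stood apart in the nucleus accumbens and 1 in the amygdala, and a score of the thalamic list as a covariate in the hippocampus. The fits were tested on simulated data with the same groups, dispersions and depths, in which 1.5-fold, 2-fold and 4-fold changes were added to known genes. No library was left out of the reported values.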

Results

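Gene expression was measured in 99 libraries of poly-A RNA, each pooled from 2 mice, in 4 brain regions. Every region had 4 libraries of resilient mice and 3 of susceptible mice given saline, 3 each of ketamine responders, ketamine non-responders and imipramine responders, and 4 of imipramine non-responders. Control mice given saline had 5 libraries per region, except the ventral hippocampus with 4. After the filter on low counts, 17517, 17718, 17758 and 18392 genes were tested in the prefrontal cortex, nucleus accumbens, ventral hippocampus and basolateral amygdala. Gene values are edgeR log2 fold changes with their standard error (SE), and list values are differences between groups in the mean log2 CPM of the list's members, or medians of the members' log2 fold changes where so named.

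Of the 36 comparisons made (9 in each region), 34 had 0 genes past an adjusted p of 0.05 in edgeR; they had 69 to 3078 genes at an unadjusted p below 0.05, and DESeq2 called 0 to 47 genes in them. Chance alone would put 876 to 920 genes below that unadjusted p, and 26 of the 36 comparisons had fewer. The calls were made in the ventral hippocampus, with 119 genes for ketamine responders and 1 gene for ketamine non-responders, both against susceptible saline mice. In simulated data with these groups and depths, edgeR recovered 47 of 67 genes changed 1.5-fold and 66 of 66 changed 4-fold for ketamine responders in the hippocampus, and 17 of 67 and 66 of 66 in the nucleus accumbens. Large real changes are not ruled out by 0 calls: Ankk1, at 3.24 in resilient against control amygdala, was not called. Among the 1080 list tests, 372 passed camera with the preset correlation. With an estimated correlation, whose median was 0.308, 0 passed (smallest adjusted p = 0.372 with an estimated correlation), and fry, which asks whether a list moves on balance one way, passed 0 (smallest adjusted p = 0.29); its version for members moving either way passed 2.

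Susceptible mice were compared with controls to ask what sets apart mice that become avoidant after defeat. Immediate early genes, which neurons switch on within minutes of activity, had lower values in susceptible mice. All 23 members of the list were below controls in the prefrontal cortex. Their mean log2 CPM was 4.47 ± 0.0785 (SD, n = 3) against 4.87 ± 0.366 in controls (n = 5). The difference was -0.395 there, -0.221 in the nucleus accumbens (18 members lower), -0.0739 in the ventral hippocampus (17 lower) and -0.253 in the amygdala (20 lower). Fos (ENSMUSG00000021250), a transcription factor gene used as a marker of neuronal activity, stood at 6.79 ± 0.592 CPM in susceptible and 15.3 ± 9.22 CPM in control prefrontal cortex (log2 fold change -1.20, SE 0.46), and at 6.52 ± 1.76 against 12.5 ± 4.14 CPM in the amygdala (-0.93, SE 0.265). Its log2 fold change was -0.77 (SE 0.445) in the nucleus accumbens and -0.58 (SE 0.281) in the hippocampus. Arc (ENSMUSG00000022602), whose product regulates glutamate receptor traffic at synapses, stood at 52.3 ± 14.1 against 107 ± 46.5 CPM in the prefrontal cortex (-1.04, SE 0.396), with -0.66 (SE 0.297) in the nucleus accumbens, -0.17 (SE 0.138) in the hippocampus and -0.56 (SE 0.239) in the amygdala. Ier2 (-0.76, SE 0.174) had the smallest p among lower genes of the prefrontal cortex.

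Camera passed the immediate early list in each region (adjusted p = 1.02e-16 in the prefrontal cortex, 1.21e-06 in the nucleus accumbens, 0.0424 in the hippocampus and 3.47e-10 in the amygdala), but adjusted p = 0.413, 0.624, 0.609 and 0.552 with an estimated correlation. Exact two-sided relabelling of libraries gave p = 0.125, 0.143, 0.0857 and 0.214. While 0 members passed over all genes, 5 passed in the prefrontal cortex and 1 in the amygdala adjusted over the list alone. The hippocampal call was lost without control replicate 1 (adjusted p = 0.188) or 2 (0.183), or without susceptible replicate 2 (0.14) or 3 (0.0932), and with the sample-number series as a covariate (0.118).

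Glucocorticoid-responsive genes, which stress hormones induce, had higher values in susceptible mice, with differences of 0.144, 0.331, 0.241 and 0.178 in the prefrontal cortex, nucleus accumbens, hippocampus and amygdala. In the nucleus accumbens the 19 genes averaged 4.51 ± 0.326 (SD, n = 3) against 4.18 ± 0.0642 in controls (n = 5). There 17 members were higher, and all 3 susceptible libraries lay above every control. Plin4 (ENSMUSG00000002831), which coats lipid droplets, was at 1.49 (SE 0.311, adjusted p = 0.714) in the prefrontal cortex and 1.91 (SE 0.587) in the nucleus accumbens. Fkbp5 (ENSMUSG00000024222), a co-chaperone of the glucocorticoid receptor, was at 0.20 (SE 0.0839), 0.20 (SE 0.177), 0.13 (SE 0.118) and 0.06 (SE 0.166), and the kinase gene Sgk1 at 0.08 (SE 0.0839), 0.30 (SE 0.227), 0.26 (SE 0.221) and 0.33 (SE 0.2). Camera gave adjusted p = 0.029, 2.34e-07, 5.04e-06 and 0.0169, and adjusted p = 0.624, 0.593, 0.633 and 0.735 with an estimated correlation. Exact relabelling gave p = 0.0357, 0.0179 (the smallest possible), 0.143 and 0.232. Over all genes 0 members passed, and 1 did adjusted over the list alone, in the prefrontal cortex. The call was lost in the prefrontal cortex without susceptible replicate 2 (median log2 fold change -0.042 in place of 0.05) or control replicate 1 or 5 (adjusted p = 0.119 and 0.145), and with the series covariate (0.0795). It was lost in the hippocampus without susceptible replicate 1 (0.0104 in place of 0.14) and in the amygdala without susceptible replicate 2 (-0.0212 in place of 0.06) or control replicate 1 or 3 (adjusted p = 0.0591 and 0.0735). In the nucleus accumbens the median was 0.0909 without susceptible replicate 3, against 0.20 with it.

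**Figure D1:**
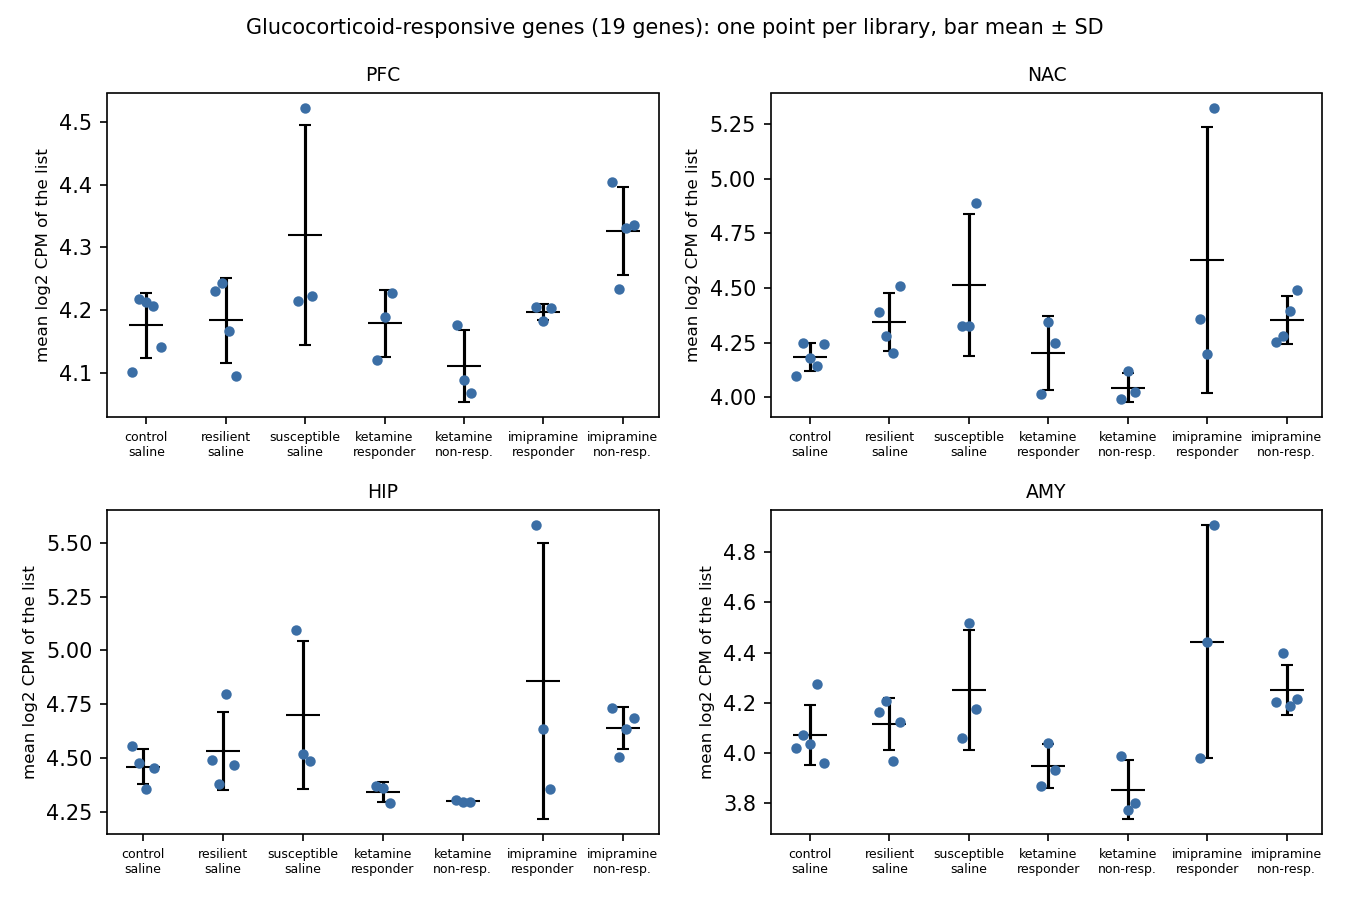
Mean log2 CPM of the 19 glucocorticoid-responsive genes (vertical axis) in each library, by condition (horizontal axis), with 1 panel per region; points are libraries and bars are the mean ± SD of the group. The 3 ketamine non-responder libraries lie below the 3 susceptible libraries in every panel.

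The other genes that were followed in susceptible mice gave no call either. Bdnf, the neurotrophin gene, was at -0.31 (SE 0.152) in the prefrontal cortex, 1.56 (SE 0.952) in the nucleus accumbens, -0.04 (SE 0.148) in the hippocampus and -0.23 (SE 0.245) in the amygdala, and the accumbens value turned to -0.351 without susceptible replicate 3. Crh, the corticotropin-releasing hormone gene, was at -0.18 (SE 0.158), -0.44 (SE 0.467), -0.19 (SE 0.277) and 0.10 (SE 0.373), and Egr1 at -0.36 (SE 0.254), -0.24 (SE 0.23), 0.04 (SE 0.0879) and -0.03 (SE 0.181) in the same order. Ttr, the transthyretin gene of the choroid plexus, was at 6.35 (SE 1.54) in the prefrontal cortex, where 1 library decided it (-0.465 without susceptible replicate 2), at 0.04 (SE 0.862) in the nucleus accumbens, at -0.78 (SE 2.07) in the hippocampus and at -3.18 (SE 1.88) in the amygdala (1.16 without control replicate 4). The choroid plexus list had a median of 1.88 in the prefrontal cortex (adjusted p = 4.95e-06, and adjusted p = 0.624 with an estimated correlation), a value that includes the same library, at a mean of 3.64 log2 CPM against 0.36 and 0.38 in the other 2. Markers of striatal projection neurons had a median of 0.61 in the amygdala (adjusted p = 3.52e-16, and adjusted p = 0.571 with an estimated correlation) but -0.11 in the hippocampus (adjusted p = 0.0077, and adjusted p = 0.777 with an estimated correlation). None of the genes with the smallest p passed. They were Epn3 (1.44, SE 0.291) in the prefrontal cortex and Gm10451 (1.12, SE 0.276) and 9130208D14Rik (-1.49, SE 0.364) in the nucleus accumbens. They were Gm9157 (1.06, SE 0.348) and Cdh1 (-4.24, SE 1.26) in the hippocampus, and Egln3 (0.61, SE 0.164) and Abcc12 (-1.64, SE 0.33) in the amygdala. edgeR called 0 genes in each region, with 543, 155, 166 and 240 at an unadjusted p below 0.05, of which 265, 133, 111 and 196 differed by at least 1.3-fold. DESeq2 called 0, 0, 0 and 1. edgeR called Epn3 in the prefrontal cortex without susceptible replicate 1 (adjusted p = 0.0469) and Plin4 without susceptible replicate 3 (adjusted p = 0.00279).

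Resilient mice, which were defeated but stayed social, were compared with controls. In the amygdala, markers of striatal projection neurons averaged 6.20 ± 0.861 log2 CPM (SD, n = 4) against 4.80 ± 0.566 in controls (n = 5), a difference of 1.4 with all 18 members higher. Among them Rgs9, a regulator of G-protein signalling, was at 1.58 (SE 0.337), Rasd2 at 0.85 (SE 0.18) and Adcy5 at 0.63 (SE 0.134). Each had adjusted p = 0.193 in edgeR. Scn4b (3.19, SE 0.718) and Drd2 (1.94, SE 0.477) were chosen after their values were seen. The list averaged 8.69 in nucleus accumbens controls. Striatal tissue in the dissection was not tested as a source. Ankk1 (3.24, SE 0.611) and Anks4b (-1.63, SE 0.323) had the smallest p. Oligodendrocyte markers, which make myelin, were higher in the amygdala as well, 5.90 ± 0.181 against 5.50 ± 0.25 (Mobp 0.51, SE 0.145), but differed by -0.225 in the prefrontal cortex, 0.126 in the nucleus accumbens and -0.126 in the hippocampus. Ependymal markers, the cells that line the ventricles, were at -0.55 ± 0.222 against 0.65 ± 1.05. In the prefrontal cortex the 12 measured genes of the mitochondrial genome had a median of -0.24, and immediate early genes a median of -0.29, among them Gadd45b (-0.44, SE 0.0982, adjusted p = 0.453).

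Camera passed these lists, with adjusted p = 2.68e-33 for the striatal, 1.05e-19 for the oligodendrocyte and 3.47e-11 for the ependymal markers in the amygdala, and 2.65e-11 for the mitochondrial and 9.23e-06 for the immediate early genes in the prefrontal cortex. None held with an estimated correlation, where adjusted p = 0.372, 0.503, 0.571, 0.503 and 0.624. The oligodendrocyte list also passed in the other regions (adjusted p = 4.07e-06, 1.38e-05 and 0.000244, and adjusted p = 0.732, 0.686 and 0.783 with an estimated correlation), in the hippocampus not without control replicate 2 or 3 (0.179 and 0.0719) or resilient replicate 4 (0.749). Exact relabelling gave p = 0.0397, 0.0476 and 0.0873 for the amygdala lists. Over all genes 0 members passed; adjusted over the list alone, 17 striatal, 14 oligodendrocyte and 7 ependymal markers and 9 mitochondrial and 4 immediate early genes did. In the hippocampus the striatal list had a difference of -0.233 (adjusted p = 0.00056, and adjusted p = 0.732 with an estimated correlation), a call that was lost without control replicate 1 (median 0.00842). The remaining genes with the smallest p were the transcript ENSMUSG00000092754 (1.19, SE 0.29) in the prefrontal cortex, Gm10451 (1.31, SE 0.253) and Xlr3b (-1.40, SE 0.382) in the nucleus accumbens, and Dcn (0.93, SE 0.271) and Pbld2 (-0.58, SE 0.152) in the hippocampus. edgeR called 0 genes in each region, with 1640, 290, 318 and 1031 at an unadjusted p below 0.05 (334, 209, 150 and 722 by at least 1.3-fold). DESeq2 called 16, 0, 0 and 47, Rgs9, Rasd2 and Adcy5 among the last (adjusted p = 0.00661, 0.0112 and 0.0119). The prefrontal count became 155 without control replicate 5, 1 without resilient replicate 3 and 292 with the sample-number series as a covariate. The amygdala count became 38 without resilient replicate 3 and 12 without control replicate 3.

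Resilient mice were then compared with susceptible mice, the pair that differs in outcome after the same stress. Glucocorticoid-responsive genes had lower values in resilient mice, with medians of -0.06 in the prefrontal cortex, -0.16 in the nucleus accumbens and -0.10 in the hippocampus, and Klf9, a transcription factor gene that glucocorticoids induce, had the smallest p among lower genes of the prefrontal cortex (-0.27, SE 0.0619, adjusted p = 0.959). Microglial markers had higher values in resilient mice by 0.0642, 0.0692, 0.194 and 0.132 in the prefrontal cortex, nucleus accumbens, hippocampus and amygdala (n = 4 against 3; exact p = 0.143, 0.429, 0.429 and 0.457). With the sample-number series as a covariate the microglial medians were 0.012, -0.0528, 0.117 and -0.0446, and only the hippocampal list passed. Oligodendrocyte markers had a median of -0.34 in the prefrontal cortex and 0.26 in the amygdala, and mural and meningeal markers one of 0.49 in the amygdala. In the hippocampus Dcn and Lum, proteoglycan genes of the meninges, were at 1.31 (SE 0.297) and 0.68 (SE 0.211). Camera gave adjusted p = 0.00284, 0.0404 and 0.00673 for the glucocorticoid-responsive list, 0.0457, 0.0209, 5.04e-06 and 0.0334 for microglia, 1.47e-11 and 9.52e-13 for oligodendrocytes and 8.12e-12 for mural cells. With an estimated correlation adjusted p = 0.605, 0.814 and 0.806, then 0.838, 0.794, 0.732 and 0.877, then 0.62 and 0.605, then 0.372. The microglial call was lost without resilient replicate 1, 2 or 4 or susceptible replicate 1 or 2 in the prefrontal cortex (adjusted p up to 0.469). It was lost without resilient replicate 4 or susceptible replicate 2 or 3 in the nucleus accumbens (up to 0.486), resilient replicate 3 in the hippocampus (0.279), and resilient replicate 1, 2 or 4 or susceptible replicate 2 or 3 in the amygdala (up to 0.598). edgeR and DESeq2 each called 0 genes in every region, with 748, 150, 369 and 254 at an unadjusted p below 0.05 (249, 117, 135 and 208 by at least 1.3-fold). The other genes with the smallest p were Gm20634 (1.65, SE 0.427) in the prefrontal cortex, Sh2d4a (1.82, SE 0.437) and 9330020H09Rik (-0.74, SE 0.202) in the nucleus accumbens, Zfpm1 (-0.34, SE 0.0921) in the hippocampus, and Abcc12 (1.48, SE 0.344) and ENSMUSG00000087218 (-1.44, SE 0.308) in the amygdala.

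Ketamine responders were compared with susceptible saline mice to ask what the drug changed in mice it helped. In the ventral hippocampus 119 genes changed: 110 rose and 9 fell. Tnnt1 (ENSMUSG00000064179), a troponin gene, rose from 0.917 ± 0.0559 CPM (SD, n = 3) to 16.5 ± 7.27 CPM (n = 3), a log2 fold change of 4.17 (SE 0.486, adjusted p = 0.000346), and was higher in 3 of 3 libraries. Foxp2 (ENSMUSG00000029563; 3.59, SE 0.711, adjusted p = 0.0228), Slc17a6 (ENSMUSG00000030500; 3.46, SE 0.688, 0.025) and Tcf7l2 (ENSMUSG00000024985; 3.43, SE 0.624, 0.0172) followed. The first and last encode transcription factors, and Slc17a6 a glutamate transporter. Fkbp5 fell from 78.3 ± 8.53 to 50.9 ± 7.55 CPM (-0.62, SE 0.127, adjusted p = 0.0212), Zbtb16, a transcription factor gene, fell (-0.54, SE 0.113, 0.0246). The remaining largest falls were Gpr161, a receptor gene of primary cilia (-0.59, SE 0.128, 0.0294), St18 (-0.57, SE 0.0942, 0.00684) and the potassium channel gene Kcng2 (-0.56, SE 0.133, 0.0483).

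The genes that rose included 8 of the 11 measured members of the list for thalamus and hypothalamus, structures next to the hippocampus. Prkcd (3.12, SE 0.553), Zic1 (2.85, SE 0.492) and Rgs16 (2.75, SE 0.412) were among them. The list's mean log2 CPM was 3.35 ± 0.972 against 1.60 ± 0.156, every responder library lay above every susceptible library, and exact p = 0.1, the smallest possible with 3 against 3. Camera gave adjusted p = 3.56e-16, and adjusted p = 0.372 with an estimated correlation. Adra1b (2.47, SE 0.412), Grm4 (1.89, SE 0.393), Calb2 (1.83, SE 0.4) and Rora (1.64, SE 0.331) rose as members of other lists. Of the mural and meningeal markers, Dcn (1.79, SE 0.31), Aldh1a2 (1.48, SE 0.297) and Col1a2 (1.08, SE 0.23) rose, 12 of 18 passed adjusted over the list alone, and the list differed by 0.694 (adjusted p = 1.23e-14, and adjusted p = 0.372 with an estimated correlation). Choroid plexus markers differed by 2.32 (2.60 ± 2.11 against 0.29 ± 0.112; adjusted p = 3.39e-10, and adjusted p = 0.624 with an estimated correlation), with 14 of 18 passing adjusted over the list alone and 0 over all genes; Otx2, a factor of the choroid plexus, was at 3.60 (SE 0.985, adjusted p = 0.123). The growth hormone gene Gh, chosen after its values were seen, was among the 9 genes that fell, with a median of 0 CPM in the ketamine libraries of the hippocampus against 1.66 CPM in the others.

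At an unadjusted p below 0.05 there were 1772 genes in the hippocampus (944 by at least 1.3-fold), against 888 by chance. DESeq2 called 250, with all 119 among them, and edgeR called 471 with the sample-number series as a covariate. Leaving out 1 library moved the edgeR count to 3, 2 or 4 (susceptible replicate 1, 2 or 3) and to 525, 307 or 13 (responder replicate 1, 2 or 3). Tnnt1, and Vipr2, chosen after its values were seen, passed without susceptible replicate 2. The other called genes named here failed without it, for example Foxp2 (adjusted p = 0.107), Rgs16 (0.0545), Dcn (0.0943) and Fkbp5 (0.0943). With the thalamic covariate, chosen after seeing the data, edgeR called 3: Tnnt1 (2.71, adjusted p = 0.00276), Rgs16 (1.06, 0.039) and Vipr2 (2.32, 0.0313). The score holds 8 called genes, Rgs16 too, so a fall is built in. Medians went from 1.64 (quartiles 1.08, 2.57) to 0.466 (0.261, 0.785) for the 110 that rose and from -0.565 to -0.398 for the 9 that fell.

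**Figure D2:**
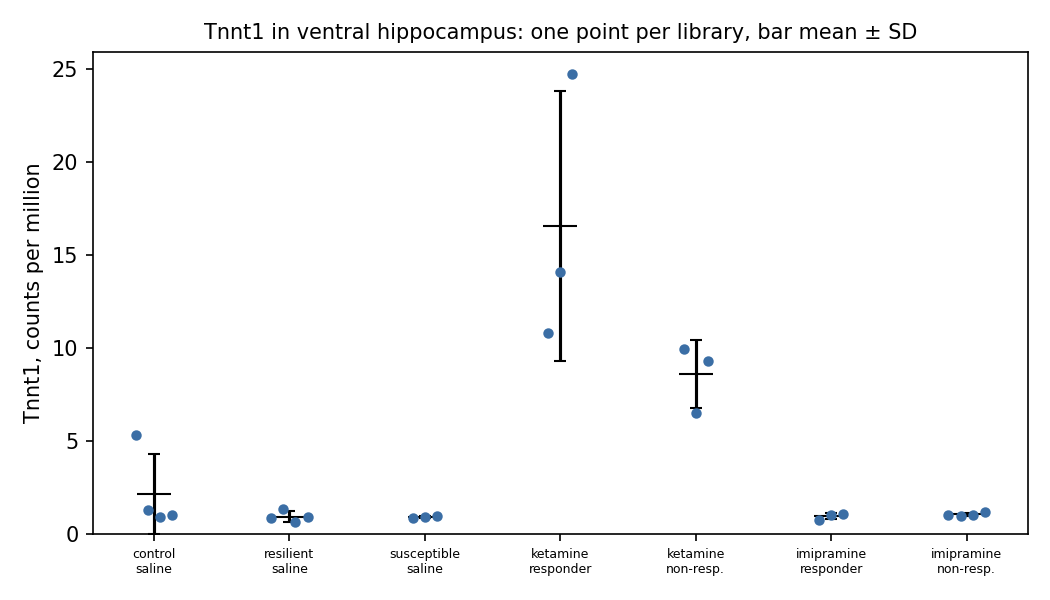
Tnnt1 level in CPM (vertical axis) in each library of the ventral hippocampus, by condition (horizontal axis). Points are libraries and bars are the mean ± SD of the group. Hippocampal ketamine responders (16.5 ± 7.27) and non-responders (8.58 ± 1.83) lie above susceptible mice (0.917 ± 0.0559).

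In the prefrontal cortex of ketamine responders, oligodendrocyte markers averaged 5.29 ± 0.213 log2 CPM (SD, n = 3) against 4.66 ± 0.139 in susceptible mice (n = 3), with all 18 members higher. The myelin genes Ermn (0.76, SE 0.165) and Fa2h (0.78, SE 0.171) each had adjusted p = 0.146 in edgeR and 0.00989 in DESeq2. The difference was 0.63 there, 0.31 in the nucleus accumbens (Cnp 0.40, SE 0.11; Ugt8a 0.52, SE 0.145), 0.134 in the hippocampus and, in the other direction, -0.212 in the amygdala. Glucocorticoid-responsive genes had lower values in responders in each region, by -0.14, -0.311, -0.36 and -0.304 in the prefrontal cortex, nucleus accumbens, hippocampus and amygdala. In the amygdala Egln3 (ENSMUSG00000035105), an oxygen-sensing prolyl hydroxylase gene, was at -1.12 (SE 0.189) and the transcript ENSMUSG00000074788 at 1.38 (SE 0.236), both with adjusted p = 0.0636 in edgeR and 6.29e-05 in DESeq2. Hif3a had the smallest p among lower genes of the nucleus accumbens (-1.54, SE 0.362), and Cdc42ep1 among higher ones (0.49, SE 0.111). Mcam (0.73, SE 0.14) and Prss22 (-0.94, SE 0.169) had them in the prefrontal cortex. There adjusted p = 0.126 and 0.12 in edgeR and 0.00212 in DESeq2.

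For oligodendrocytes camera gave adjusted p = 3.11e-31, 1.02e-16, 0.0563 and 6.54e-06 in the same order of regions, and adjusted p = 0.372, 0.503 and 0.732 with an estimated correlation where it had passed. Exact p = 0.1, the smallest possible, in the prefrontal cortex, 0.2 in the nucleus accumbens and 0.3 in both other regions. Adjusted over the list alone, 17 members passed in the prefrontal cortex and 6 in the nucleus accumbens, against 0 over all genes; the hippocampal list passed without responder replicate 1 (adjusted p = 0.0175) or susceptible replicate 2 (0.00487). For glucocorticoid-responsive genes camera gave adjusted p = 0.000717, 6.5e-05, 7.82e-08 and 6.52e-06, and adjusted p = 0.546, 0.624, 0.624 and 0.586 with an estimated correlation; exact p = 0.3, 0.3, 0.1 and 0.1. The call was lost in the prefrontal cortex without susceptible replicate 2 (median -0.0501) and in the nucleus accumbens without susceptible replicate 3 (-0.185). Choroid plexus markers differed by 1.39 in the amygdala and -1.08 in the prefrontal cortex, each through 1 library: the medians were -0.294 without responder replicate 2 of the amygdala and 0.00255 without susceptible replicate 2 of the prefrontal cortex (adjusted p = 0.732 and 0.624 with an estimated correlation and all libraries). edgeR called 0 genes in the prefrontal cortex, nucleus accumbens and amygdala, with 1082, 490 and 776 at an unadjusted p below 0.05 (477, 345 and 557 by at least 1.3-fold). DESeq2 called 47, 0 and 15. The prefrontal count became 27 with the sample-number series as a covariate, 2 without responder replicate 2 or susceptible replicate 3 and 1 without susceptible replicate 1. The amygdala count became 1 without susceptible replicate 1 (Egln3, adjusted p = 0.000472).

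**Figure D3:**
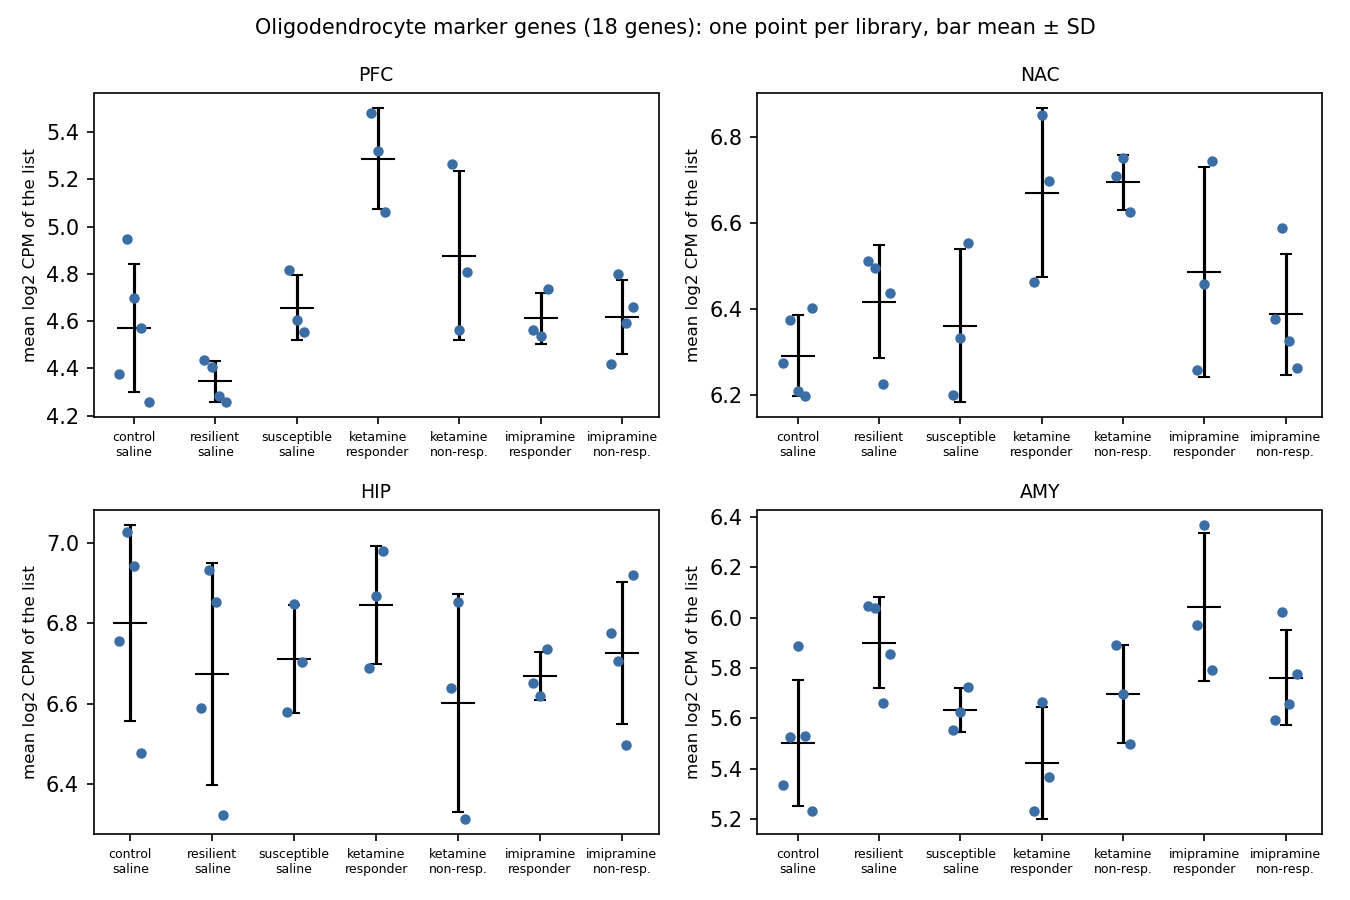
Mean log2 CPM of the 18 oligodendrocyte markers (vertical axis) in each library, by condition (horizontal axis), with 1 panel per region; points are libraries and bars are the mean ± SD of the group. Prefrontal ketamine responders (5.29 ± 0.213) lie above susceptible mice (4.66 ± 0.139).

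Ketamine non-responders, given the same drug without a change in behaviour, were compared with the same susceptible mice. Glucocorticoid-responsive genes were lower by -0.209, -0.469, -0.402 and -0.397 in the prefrontal cortex, nucleus accumbens, hippocampus and amygdala (n = 3 against 3). All 3 non-responder libraries lay below all 3 susceptible libraries in each region, with 17, 18, 19 and 17 of the 19 members lower. Fkbp5 was at -0.47 (SE 0.0949), -0.65 (SE 0.199) and -0.55 (SE 0.127) in the first 3 regions, Plin4 at -1.56 (SE 0.36) in the prefrontal cortex and -2.32 (SE 0.696) in the nucleus accumbens, and Zbtb16 at -0.47 (SE 0.114) in the hippocampus. Heat shock and chaperone genes were higher by 0.175, 0.154, 0.17 and 0.236 in the same order. Members with the smallest p were, in the hippocampus, Hspa5, a chaperone gene of the endoplasmic reticulum, at 0.56 (SE 0.144), Pdia4 at 0.45 (SE 0.118) and Manf at 0.40 (SE 0.11), and Sdf2l1 at 0.56 (SE 0.124, adjusted p = 0.378) in the prefrontal cortex. In the hippocampus Tnnt1 rose to 8.58 ± 1.83 CPM (3.22, SE 0.485, adjusted p = 0.0318, higher in 3 of 3 libraries), the 1 gene called there. Thalamic markers moved with it in these libraries, with a median of 1.44 (adjusted p = 5.54e-10, and adjusted p = 0.546 with an estimated correlation; 6 of 11 adjusted over the list alone).

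For glucocorticoid-responsive genes camera gave adjusted p = 2.88e-06, 1.6e-09, 5.08e-12 and 4.74e-06, and adjusted p = 0.372, 0.503, 0.571 and 0.571 with an estimated correlation. Exact p = 0.1 in each region, the smallest possible, and no single library ended the camera call. There were 6, 3, 2 and 0 lower members past the test adjusted over the list alone, and 0 over all genes. For heat shock genes camera gave adjusted p = 6.06e-10, 0.00595, 1.74e-06 and 3.87e-06, adjusted p = 0.413, 0.777, 0.605 and 0.673 with an estimated correlation, and exact p = 0.1, 0.2, 0.2 and 0.2. Adjusted over the list alone, 4 heat shock genes passed in the prefrontal cortex and 5 in the hippocampus; the call in the nucleus accumbens was lost without susceptible replicate 3 (adjusted p = 0.0963) or non-responder replicate 3 (0.19). Oligodendrocyte markers had a median of 0.30 in the nucleus accumbens (adjusted p = 4.92e-17, and adjusted p = 0.503 with an estimated correlation; 10 of 18 adjusted over the list alone) and of -0.10 in the hippocampus (adjusted p = 0.0288, and adjusted p = 0.877 with an estimated correlation). Interferon and antigen presentation genes had a median of 0.29 in the prefrontal cortex (adjusted p = 2.93e-08, and adjusted p = 0.372 with an estimated correlation). edgeR called 0, 0, 1 and 0 genes, with 761, 636, 1018 and 561 at an unadjusted p below 0.05 (324, 448, 557 and 413 by at least 1.3-fold), and DESeq2 called 7, 1, 30 and 7. The Tnnt1 call was lost without susceptible replicate 1 (adjusted p = 0.448), 2 (0.206) or 3 (0.201) or non-responder replicate 1 (0.0966). It was also lost without the filter or with the series covariate (0.108 and 0.0574), and 5 genes were called without non-responder replicate 3. Genes with the smallest p elsewhere were Gkn3 (0.87, SE 0.185) and Klhl40 (-0.64, SE 0.123) in the prefrontal cortex, Mcam (0.40, SE 0.0907) and Hif3a (-1.81, SE 0.36) in the nucleus accumbens, and Cfap97d2 (1.19, SE 0.257) and Egln3 (-1.04, SE 0.189) in the amygdala. edgeR called 1 gene in the prefrontal cortex without susceptible replicate 1 and 2 without replicate 3, and Egln3 in the amygdala without susceptible replicate 1 (adjusted p = 0.00132).

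Responders to ketamine were compared with non-responders to ask what goes with response at the same treatment. In the prefrontal cortex and amygdala the groups share no sample-number series (1 and 2 for responders, 3, 4 and 5 for non-responders), so response and series cannot be separated there. Oligodendrocyte markers had higher values in responders in the prefrontal cortex (all 18 members higher, median 0.40) and hippocampus (median 0.21), and lower ones in the amygdala (all 18 lower, median -0.27). Choroid plexus and ependymal markers had medians of 3.90 and 1.56 in the amygdala, values not computed without responder replicate 2, whose choroid plexus mean was 5.22 log2 CPM against 0.19 and 0.24 in the other responders. Folr1, a folate receptor gene of the choroid plexus, stood at 8.05 ± 13.7 CPM in amygdala responders (n = 3) and 0.0125 ± 0.0217 CPM in non-responders (n = 3), a spread that comes from 1 responder library. Heat shock genes had medians of -0.08 in the prefrontal cortex, -0.08 in the hippocampus and -0.21 in the amygdala. Other lists moved in the same libraries. In the hippocampus thalamic markers had a median of 1.17 and hippocampal and glutamatergic neuron markers -0.22 and -0.17 (adjusted p = 6.18e-05, 0.000164 and 0.000839, and adjusted p = 0.624, 0.571 and 0.605 with an estimated correlation). In the amygdala ribosomal, oxidative phosphorylation and microglial genes had medians of -0.24, -0.25 and -0.30 (adjusted p = 2.26e-09, 8.12e-12 and 2.52e-05, and adjusted p = 0.838, 0.794 and 0.735 with an estimated correlation). Camera gave adjusted p = 4.23e-17, 8.69e-06 and 8.16e-10 for oligodendrocytes, 2.55e-10 and 2.27e-07 for choroid plexus and ependyma and 7.66e-05, 0.0068 and 2.72e-07 for heat shock. With an estimated correlation adjusted p = 0.552, 0.732 and 0.624, then 0.624 and 0.624, then 0.605, 0.751 and 0.624. Adjusted over the list alone, 11 prefrontal oligodendrocyte, 16 choroid plexus and 7 ependymal markers passed, the last 2 lists with that library included. edgeR called 0 genes in each region, with 795, 69, 1233 and 503 at an unadjusted p below 0.05 (336, 53, 559 and 457 by at least 1.3-fold), and DESeq2 called 0, 0, 0 and 7; in the hippocampus edgeR called 3 without responder replicate 1. Genes with the smallest p were Trim59 (0.60, SE 0.139) and Angptl6 (-0.45, SE 0.111) in the prefrontal cortex, Ttll13 (0.54, SE 0.194) and ENSMUSG00000087594 (-1.43, SE 0.478) in the nucleus accumbens, Mob3a (0.55, SE 0.121) and BX649560.1 (-0.43, SE 0.102) in the hippocampus, and Tspan11 (1.61, SE 0.311) and Gm22574 (-2.44, SE 0.644) in the amygdala.

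Imipramine responders were compared with susceptible saline mice and with imipramine non-responders. Against non-responders (n = 3 against 4), ribosomal protein genes had higher values in the nucleus accumbens and amygdala, with medians of 0.78 and 0.70 over the 79 measured genes, and nuclear genes of oxidative phosphorylation had medians of 0.70 and 0.69 over 78 genes; in the prefrontal cortex the medians were -0.10 and -0.07. These values came from 1 responder library per region. Without responder replicate 3 of the nucleus accumbens and replicate 2 of the amygdala, libraries left out after seeing the data, the ribosomal medians were -0.0647 and -0.0907 and the oxidative phosphorylation medians -0.0748 and -0.0914. In the prefrontal cortex immediate early genes had a median of -0.36 against non-responders. Glucocorticoid-responsive genes had medians of 0.21 in the hippocampus, 0.25 in the amygdala and -0.07 in the prefrontal cortex, and one of 0.40 in the nucleus accumbens that did not pass (adjusted p = 0.115); the amygdala and accumbens values include the libraries that stood apart. Cell markers moved too. In the amygdala the medians were 1.02 for striatal neurons (18 of 18 higher), 2.44 for choroid plexus (18 of 18) and 0.23 for oligodendrocytes (17 of 18), with adjusted p = 2.01e-06, 0.00434 and 0.000367, and adjusted p = 0.732, 0.87 and 0.777 with an estimated correlation. In the hippocampus they were 0.87 for choroid plexus (17 of 18 higher) and -0.09 for microglia (17 of 18 lower), with adjusted p = 0.0044 and 0.0136, and adjusted p = 0.87 for both with an estimated correlation. Dpysl2, a cytoskeletal regulator gene (1.18, SE 0.315), and ENSMUSG00000086673 (-1.50, SE 0.327) had the smallest p against susceptible mice in the nucleus accumbens. They were Gm14719 (1.95, SE 0.399) and Egln3 (-0.99, SE 0.19, adjusted p = 0.395) in the amygdala. They were Igkc (2.59, SE 0.67) and Mfrp (-3.25, SE 0.857) in the prefrontal cortex and ENSMUSG00000087101 (2.01, SE 0.422) and Gm10651 (-1.03, SE 0.293) in the hippocampus. Against non-responders they were Gm11944 (1.37, SE 0.304) and Dscc1 (-1.67, SE 0.379) in the prefrontal cortex, Ttr (3.82, SE 0.82) and Nup210l (-0.95, SE 0.243) in the nucleus accumbens, Pi16 (0.79, SE 0.203) and Gm4353 (-0.90, SE 0.258) in the hippocampus, and Gm15892 (1.52, SE 0.33) and Zbtb40 (-0.55, SE 0.127) in the amygdala.

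Camera gave adjusted p = 2.27e-16 and 1.39e-16 for ribosomal genes in the nucleus accumbens and amygdala and 1.69e-08 for immediate early genes in the prefrontal cortex. For glucocorticoid-responsive genes it gave 2.98e-05, 0.0155 and 0.00981 in the hippocampus, amygdala and prefrontal cortex. These became adjusted p = 0.738, 0.738, 0.605, 0.686, 0.732 and 0.624 with an estimated correlation, and 0.751 and 0.742 for oxidative phosphorylation. Of the members, adjusted over the list alone, 73 and 70 ribosomal and 63 and 64 oxidative phosphorylation genes passed, against 0 over all genes. Against susceptible mice edgeR called 0 genes in each region, with 345, 2060, 192 and 2251 at an unadjusted p below 0.05 (197, 1645, 139 and 1781 by at least 1.3-fold), and DESeq2 called 0, 0, 0 and 1. Against non-responders edgeR and DESeq2 called 0 genes in each region, with 830, 3078, 247 and 2816 at an unadjusted p below 0.05 (349, 2256, 136 and 2009 by at least 1.3-fold). Without the library that stood apart, the unadjusted counts were 501 and 268 in the nucleus accumbens and 863 and 636 in the amygdala, against 886 and 920 by chance. Leaving out another responder instead let edgeR call 1395 genes (replicate 1) or 405 (replicate 2) in the nucleus accumbens and 1086 (replicate 1) in the amygdala against susceptible mice. Against non-responders it let edgeR call 3422 (replicate 1) or 2346 (replicate 2) in the nucleus accumbens and 2143 (replicate 1) or 1296 (replicate 3) in the amygdala. Without susceptible replicate 1 edgeR called 1 gene in the amygdala, Egln3 (adjusted p = 0.00269).

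Imipramine non-responders (n = 4) were compared with susceptible saline mice (n = 3). Immediate early genes had higher values in the prefrontal cortex, with a median of 0.36, and interferon and antigen presentation genes had a median of 0.60 in the hippocampus. Microglial markers were higher by 0.139, 0.135, 0.152 and 0.23 in the cortex, accumbens, hippocampus and amygdala (exact p = 0.114, 0.143, 0.6 and 0.543). Among genes with the smallest p were ENSMUSG00000085480 (-1.26, SE 0.297) in the prefrontal cortex, 9130208D14Rik (1.63, SE 0.369) and ENSMUSG00000086673 (-1.29, SE 0.29) in the nucleus accumbens, ENSMUSG00000087101 (1.47, SE 0.425) and Gm7535 (-1.40, SE 0.465) in the hippocampus, and Il11 (1.47, SE 0.331) and ENSMUSG00000087421 (-1.63, SE 0.458) in the amygdala. Camera gave adjusted p = 9.05e-13 and 8.16e-10 for the first 2 lists and 7.45e-07, 7.41e-06, 2.89e-06 and 0.000288 for microglia. With an estimated correlation adjusted p = 0.503 and 0.624, then 0.605, 0.624, 0.701 and 0.777. The microglial call was lost in the hippocampus without non-responder replicate 4 (median 0.0103) and in the amygdala without non-responder replicate 2 (0.0638) or susceptible replicate 2 (adjusted p = 0.0929), or with the series covariate (0.0692). edgeR and DESeq2 called 0 genes in each region, with 743, 130, 169 and 255 at an unadjusted p below 0.05 (329, 98, 122 and 204 by at least 1.3-fold).

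Whether a difference varied between regions was tested by gene. For resilient against control mice, 23 genes varied, and the change was largest in the amygdala for 20 of them, in the nucleus accumbens for 2 and in the hippocampus for 1. These 23 include 8 markers of striatal projection neurons; chosen after their values were seen, Scn4b was at 3.19 in the amygdala and -0.07 in the hippocampus (adjusted p = 0.000689). For ketamine responders against susceptible mice 126 genes varied, with the largest change in the hippocampus for 99, among them 62 of the genes that rose there and 7 thalamic markers. Rgs16 was at 2.75 in the hippocampus and 0.02 in the amygdala (adjusted p = 2.64e-07), and Tnnt1 at 4.17 in the hippocampus and -1.66 in the nucleus accumbens (adjusted p = 1.33e-06). For susceptible against control mice and for imipramine responders against susceptible mice edgeR found 0 such genes, with 197 and 1110 at an unadjusted p below 0.05 and 951 by chance; DESeq2 was not run for this test. With 1 library left out the count of 23 moved between 5 and 81 and that of 126 between 31 and 197.

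Differences that share no library were correlated across genes, which are not independent replicates. Susceptible against control and ketamine responder against non-responder differences had Pearson r = 0.031 in the prefrontal cortex, -0.00148 in the nucleus accumbens, -0.152 in the hippocampus and -0.176 in the amygdala (exact two-sided p = 0.771, 0.984, 0.137 and 0.28). Genes with an unadjusted p below 0.05 in both numbered 30, 1, 28 and 27 (24.6, 0.604, 11.5 and 6.56 by chance), with 10, 1, 18 and 23 in opposite directions. In the amygdala Krt2 was at -3.52 (SE 0.839) in susceptible mice and 3.42 (SE 0.842) in responders. For imipramine r was -0.0195, 0.117, -0.0459 and 0.0613, and 42, 14, 6 and 22 genes were below that p in both (25.7, 26.9, 2.31 and 36.7 by chance), with 23, 8, 4 and 2 in opposite directions. Along the resilience difference r was -0.17, 0.013, -0.0633 and -0.277 for ketamine (smallest exact p = 0.0952) and -0.0826, -0.054, 0.0106 and 0.0573 for imipramine. For ketamine 147, 1, 37 and 113 genes were below that p in both (74.4, 1.13, 22.1 and 28.2 by chance), with 8, 1, 8 and 9 in the same direction; for imipramine they were 87, 19, 5 and 119 (77.7, 50.4, 4.42 and 158 by chance), with 21, 1, 1 and 112. Between the responder differences of both drugs r was 0.18, 0.115, 0.083 and -0.261, with 53, 2, 20 and 49 genes (37.7, 12, 17.2 and 77 by chance), 43, 1, 15 and 24 of them in the same direction. The imipramine counts in the nucleus accumbens and amygdala, the 112 among them, include the libraries that stood apart and were not made without them. None of the 20 correlations passed after adjustment (smallest adjusted p = 0.814). The accumbens value for susceptibility and ketamine ranged from -0.264 (without non-responder replicate 1) to 0.252 (without non-responder replicate 2), and the amygdala value between the drugs turned to 0.294 without the imipramine responder library that stood apart.

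Differences of each drug group from susceptible mice and of susceptible mice from controls share the 3 susceptible libraries, which pulls their correlation below 0 when nothing changed. Over 16 such pairs r ranged from -0.168 to -0.662, and 200 simulations of unchanged groups gave -0.534 to -0.598. The observed covariance lay above the simulated one in each pair (0 below), by 0.000184 to 0.0319. In 3 pairs r was below the simulated value. The simulated spread pooled all groups, libraries standing apart too, so nothing is concluded.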

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

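The tests of the thalamic score, the drug-response state, the imipramine libraries that stood apart, transcript length, single susceptible libraries and pituitary hormones were chosen only after the result was seen, as were the other splits for ketamine responders against susceptible mice in the hippocampus. The test of ketamine acting alike in each region and the remaining splits were not.

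In the ventral hippocampus, 110 genes rose in ketamine responders, among them 8 thalamic markers. Ketamine acting on the same genes in each region is argued against, since their median log2 fold change in responders was 0.0216 in the prefrontal cortex, -0.0348 in the nucleus accumbens and 0.0381 in the amygdala. Tissue from the neighbouring thalamus may be a source: over the 18 hippocampal libraries without ketamine, the mean of the 102 other genes followed the thalamic score (r = 0.882, permutation p = 0.00827), but r was 0.284 (p = 0.283) without the 2 farthest libraries, so it stays open. Control replicate 1 had a thalamic score of 1.07 and Tnnt1 at 5.34 CPM. Drug response stays open: the genes scored 0.428 to 0.853 in non-responders. Without ketamine the most was -0.262, bar control replicate 1 (0.662). Their median against the shared susceptible libraries was 0.789 (lower quartile 0.484), partly built in. Ketamine acting in this region alone was not tested, as drug groups and dissection are confounded.

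Imipramine responders had 2060 to 3078 genes at an unadjusted p below 0.05 in the nucleus accumbens and 2251 to 2816 in the amygdala, with 0 called by edgeR and 0 to 1 by DESeq2. A single library in each region may be the cause, since without it the counts were at most 863, below the 886 and 920 of chance. Transcript length bias of that library may be part of it: Spearman's rho between exonic length and deviation from the region's mean was -0.447 in the nucleus accumbens (-0.231 to 0.253 in the other libraries) and -0.47 in the amygdala (-0.407 to 0.309). No biological explanation was tested for these libraries.

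Glucocorticoid-responsive genes were higher in susceptible mice than in controls and lower in ketamine libraries than in susceptible mice. Both differences use the same 3 susceptible libraries per region, which alone pulls them to opposite signs. A single susceptible library could account for the first difference in 3 of the 4 regions, where leaving it out ended the call, but the call stayed in the nucleus accumbens (median 0.0909 without susceptible replicate 3), which leaves this open. Handling of the ketamine libraries apart from the others also stays open, because transcripts of pituitary hormones, chosen after their values were seen, differed. Gh had a median of 0 CPM in 24 ketamine libraries and 1.99 CPM in the 75 others (permutation p = 1e-05, the smallest possible), with p = 1e-05 for Prl, 0.0017 for Pomc, 0.00072 for Cga and 0.433 for Tshb. An effect of ketamine itself on these transcripts was not tested, and the design cannot separate it from handling.

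A test for 1 library far from the rest of its group was run on 108 combinations of a value and a group of 4 or 5 libraries, and not on groups of 3. It found 11, where chance finds about 1 in 20, or 5.4. In the prefrontal cortex Sgk1 was at 51.7 CPM in 1 control library (next 41.2) and Ttr at 59.8 CPM in 1 imipramine non-responder (next 1.22). In the nucleus accumbens 1 control library had a total of 33.6 M counts (next 27.9), Crh was at 3.51 CPM in 1 resilient library (next 2.34) and Fkbp5 at 55.5 CPM in 1 imipramine non-responder (next 49.8). In the hippocampus Arc was at 59.9 CPM in 1 resilient library (next 72.6), Ttr at 898 CPM in 1 resilient library (next 7.1) and Egr1 at 92 CPM in 1 imipramine non-responder (next 102). In the amygdala Ttr was at 699 CPM in 1 control library (next 10.1), Bdnf at 41.5 CPM in 1 resilient library (next 23.3) and Egr1 at 132 CPM in 1 imipramine non-responder (next 111).

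Between regions, 23 genes (8 striatal markers, dissection untested) varied for resilient against control mice and 126 for ketamine responders against susceptible mice. For the 23, of 40 labellings 1, the real one, gave as many (highest other 3). That is the smallest share possible, so over 4 tests chance is not excluded. Nor is it for the 126, as 2 of 40 did, the real one included (highest other 128). For susceptible against control and imipramine responder against susceptible mice edgeR found 0 (40 of 40 as many; highest other 8 and 5250), with 197 and 1110 at an unadjusted p below 0.05; DESeq2 was not run. Relabellings that call so many genes point to a structure of the samples.

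Other splits of the same libraries, real value first and highest other second, follow in the order prefrontal cortex, nucleus accumbens, hippocampus and amygdala, with splits as large in brackets (of 35 for the last 3 comparisons). For passing lists, taken singly, the share of splits as large was below 0.05 in 2 comparisons. These were resilient against susceptible mice in the prefrontal cortex and hippocampus (13 against 12 in each, 1 of 35 splits). As 20 comparisons were tested in this way, about 1 such share would come by chance, and 0 of the lists pass with an estimated correlation. Chance cannot be excluded for the other comparisons with 35 splits or more, nor for any count of unadjusted or called genes in them. Unadjusted counts for susceptible against control mice were 543 against 3952 (50 of 56), 155 against 1134 (45 of 56), 166 against 800 (34 of 35) and 240 against 1872 (50 of 56). Passing lists there were 12 against 14 (6 of 56), 12 against 13 (5 of 56), 13 against 15 (3 of 35) and 12 against 17 (24 of 56). Unadjusted counts for resilient against control mice were 1640 against 2903 (23 of 100), 290 against 1149 (30 of 100), 318 against 2456 (32 of 35) and 1031 against 2637 (12 of 100). Passing lists there were 7 against 13 (61 of 100), 9 against 11 (45 of 100), 11 against 15 (10 of 35) and 9 against 16 (84 of 100). Unadjusted counts for resilient against susceptible mice were 748 against 1407 (6), 150 against 1707 (33), 369 against 1411 (21) and 254 against 973 (16). Passing lists there were 13 against 12 (1), 8 against 12 (21), 13 against 12 (1) and 9 against 14 (18). Unadjusted counts for imipramine non-responders against susceptible mice were 743 against 1998 (17), 130 against 2059 (29), 169 against 1201 (33) and 255 against 901 (20). Passing lists there were 7 against 12 (22), 11 against 13 (7), 9 against 14 (23) and 10 against 17 (20). Unadjusted counts for imipramine responders against non-responders were 830 against 2249 (14), 3078 against 5452 (17), 247 against 2822 (35) and 2816 against 5853 (15). Passing lists there were 6 against 10 (28), 4 against 16 (35), 9 against 14 (22) and 13 against 16 (9).

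Called genes numbered 0 in each real split of these 5 comparisons (edgeR; unadjusted counts are given above, and DESeq2 called 0 to 47), so all 56, 35 or 100 splits gave as many. The highest others were 746, 0, 0 and 3 for susceptible and 444, 0, 4 and 36 for resilient against control mice, 0, 1, 1 and 1243 for imipramine responders against non-responders, and 0 elsewhere. Splits that call 444 to 1243 genes point to a structure of the samples.

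For the 4 comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. Ketamine responders against susceptible mice had 1082 against 1153, 490 against 1717, 1772 against 1621 and 776 against 756 unadjusted, and 12 against 10, 9 against 12, 11 against 15 and 11 against 11 lists. Ketamine non-responders against susceptible mice had 761 against 989, 636 against 1696, 1018 against 609 and 561 against 817 unadjusted, and 17 against 13, 15 against 14, 12 against 11 and 11 against 15 lists. Ketamine responders against non-responders had 795 against 927, 69 against 701, 1233 against 2628 and 503 against 731 unadjusted, and 9 against 11, 10 against 16, 15 against 16 and 10 against 14 lists. Imipramine responders against susceptible mice had 345 against 1274, 2060 against 5513, 192 against 890 and 2251 against 5133 unadjusted, and 9 against 14, 6 against 13, 6 against 10 and 12 against 13 lists. Called genes were 119 against 0 for ketamine responders and 1 against 0 for ketamine non-responders in the hippocampus. The highest others were 134 in the hippocampus for ketamine responders against non-responders and 969 in the nucleus accumbens for imipramine responders against susceptible mice, where the real counts were 0 in edgeR and DESeq2 with 1233 and 2060 unadjusted; these too point to a structure of the samples.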

How the results depend on the processing

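The alternatives that left out the libraries standing apart and used the thalamic score were tests chosen only after the result was seen, and the others were set beforehand. No paired analysis was possible because the labels give no replicate numbers shared between conditions; the 5 series into which the sample numbers fall were used as a covariate instead. For each change named below, the cause was not tested, except that an estimated correlation makes the list test stricter by construction. Leaving out 1 of 3 libraries leaves 2, and the spread is then pooled over the groups of the region.

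Without counting single libraries left out, 703 values of named genes, 166 lists and 57 correlations kept their side of the threshold and direction, and 151 counts of called genes, 14 counts of region differences and 3 totals of lists stayed within 1.5-fold. Another 35 gene values and 2 lists passed only under the alternative, and 25 and 64 only as reported; 17 counts and 2 region counts were higher, and 3 counts and 1 total of lists lower. In all 2 gene values, 8 lists (by the direction of the test) and 9 correlations changed sign. With an estimated correlation 0 lists passed, against 372 as reported; in total 371 passed with median-ratio scaling, 360 with the series covariate, 388 without the libraries standing apart and 350 to 387 with 1 library left out.

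DESeq2 called 250 genes for ketamine responders in the hippocampus (119 in edgeR), 47 in the prefrontal cortex and 15 in the amygdala; 30 for ketamine non-responders in the hippocampus, 7 in the prefrontal cortex, 1 in the nucleus accumbens and 7 in the amygdala; 7 for ketamine responders against non-responders in the amygdala. It called 16 for resilient against control mice in the prefrontal cortex and 47 in the amygdala, 1 for susceptible against control mice in the amygdala and 1 for imipramine responders against susceptible mice there. With the series covariate edgeR called 292 for resilient against control mice in the prefrontal cortex, 27 and 471 for ketamine responders in the prefrontal cortex and hippocampus, and 0 for non-responders in the hippocampus (1018 unadjusted as reported, 30 in DESeq2). Without a filter it called 1 for ketamine responders in the prefrontal cortex and 0 for non-responders in the hippocampus. The thalamic score left 3 for ketamine responders in the hippocampus. Without the libraries standing apart 6 were called for ketamine responders against susceptible mice in the amygdala, and 0 in both imipramine responder comparisons (863 and 636 unadjusted). Region differences of resilient mice numbered 35 with the series covariate and 59 without the libraries standing apart.

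Correlations that changed sign were, for resilience and imipramine response, 0.0823 in the prefrontal cortex and -0.0775 in the hippocampus with the series removed. For susceptibility and ketamine response in the nucleus accumbens, rho was 0.00864 and r 0.0106 over genes with an average log2 CPM of at least 3. For susceptibility and imipramine response r was -0.0832 in the nucleus accumbens without the libraries standing apart and 0.057 in the hippocampus with the series removed. Between the drugs it was -0.271 (series removed) and -0.158 (libraries standing apart left out) in the nucleus accumbens and 0.294 in the amygdala, left out likewise. Lists that changed sign were microglia in resilient against susceptible mice with the series covariate (-0.0528 in the nucleus accumbens, -0.0446 in the amygdala). In imipramine responders against non-responders without the libraries standing apart, they were ribosomal genes (-0.0647 in the nucleus accumbens, -0.0907 in the amygdala) and oxidative phosphorylation (-0.0748 and -0.0914). With the thalamic score in resilient hippocampus ependymal markers turned from 0.14 to -0.105; for striatal markers the test changed direction while the median stayed below 0 (-0.17 and -0.0154). Bdnf and Crh in susceptible hippocampus changed to 0.103 and 0.154 with the series covariate.

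With each library left out in turn, counts of called genes ranged as follows. Susceptible against control mice had 0 to 1 in the prefrontal cortex. Resilient against control mice had 0 to 155 there and 0 to 38 in the amygdala. Ketamine responders had 0 to 2 in the prefrontal cortex, 2 to 525 in the hippocampus and 0 to 1 in the amygdala, non-responders 0 to 2, 0 to 5 and 0 to 1, and responders against non-responders 0 to 3 in the hippocampus. Imipramine responders had 0 to 1395 in the nucleus accumbens and 0 to 1086 in the amygdala against susceptible mice, and 0 to 3422 and 0 to 2143 against non-responders. Region differences ranged from 0 to 1 for susceptible (1 without amygdala control replicate 2), 5 to 81 for resilient, 31 to 197 for ketamine responder and 0 to 3 for imipramine responder mice (3 without nucleus accumbens responder replicate 2, 1 without amygdala responder replicate 3).

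Correlations ranged, for susceptibility and ketamine response, from -0.0538 to 0.0884 in the prefrontal cortex and -0.264 to 0.252 in the nucleus accumbens. For susceptibility and imipramine response they ranged from -0.148 to 0.0639, -0.0832 to 0.22, -0.0955 to 0.0117 and -0.00158 to 0.109 in the 4 regions. For resilience they ranged from -0.333 to 0.228 in the nucleus accumbens and -0.147 to 0.0824 in the hippocampus with ketamine, and from -0.168 to 0.0555 and -0.0607 to 0.135 with imipramine. Between the drugs they ranged from -0.158 to 0.208 in the nucleus accumbens, -0.00465 to 0.172 in the hippocampus and -0.389 to 0.294 in the amygdala.

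Medians of lists whose test changed direction ranged, in imipramine responders against non-responders, from -0.0647 to 1.07 and -0.0907 to 0.978 for ribosomal genes in the nucleus accumbens and amygdala, and from -0.0748 to 1.01 and -0.0914 to 0.969 for oxidative phosphorylation. In ketamine responders they ranged from 0.0377 to 0.239 for thalamic markers in the amygdala, from -2.44 to 0.00255 and -0.294 to 4.44 for choroid plexus in the prefrontal cortex and amygdala, and from -0.213 to 0.268 for mural cells in the nucleus accumbens. In resilient against control mice they ranged from -0.101 to 0.0188 for striatal markers in the nucleus accumbens and from -0.243 to 0.00382 for ependyma in the prefrontal cortex. Genes of susceptible against control mice ranged from -0.0307 to 0.169 and -0.0867 to 0.451 for Sgk1 in the prefrontal cortex and hippocampus, from -0.465 to 7.44, -0.216 to 0.191 and -3.57 to 1.16 for Ttr in the prefrontal cortex, nucleus accumbens and amygdala, and from -0.351 to 2.07 and -0.0886 to 0.0362 for Bdnf in the nucleus accumbens and hippocampus. Egr1 ranged from -0.0114 to 0.0869 in the hippocampus and -0.137 to 0.101 in the amygdala, Fkbp5 from -0.0417 to 0.128 and Crh from -0.117 to 0.276 in the amygdala. Kcnj13 in amygdala ketamine responders ranged from -0.037 to 6.78. Counts were not thinned to test depth. In simulated data for ketamine responders, recovery of genes changed 1.5-fold was 53 of 67 in the prefrontal cortex and 18 of 67 in the amygdala, where the median total was higher.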

Other observations

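No test in this part was chosen only after the result was seen, and all its lists were set beforehand; the 2 lists described first were picked from their results. Markers of oligodendrocyte precursors, the dividing cells that give rise to myelin-forming cells, had higher values in ketamine responders than in susceptible mice (n = 3 against 3), with medians of 0.22 in the prefrontal cortex (8 of 10 members higher) and 0.25 in the nucleus accumbens (10 of 10). Markers of mature oligodendrocytes moved with them, by 0.63 and 0.31. Olig2, a transcription factor gene of both stages, was at 0.41 (SE 0.108, edgeR adjusted p = 0.243) and 0.34 (SE 0.12), and Sox10 at 0.33 (SE 0.127) and 0.41 (SE 0.104). In non-responders the medians were 0.14 and 0.24, but both groups were compared with the same 3 susceptible libraries per region, which alone makes them agree. In camera adjusted p = 5.26e-05 and 3.12e-06 for responders and 0.0204 and 5.68e-07 for non-responders, but adjusted p = 0.372, 0.503, 0.571 and 0.413 with an estimated correlation. Adjusted over the list alone 2, 2, 2 and 3 members passed, and 0 over all genes.

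Genes of cholesterol synthesis in the nucleus accumbens had medians of 0.12 in susceptible (n = 3; 20 of 23 members higher) and 0.15 in resilient mice (n = 4; 22 of 23) against the same 5 controls, which alone makes the 2 agree. Stard4, a sterol carrier gene, was at 0.14 (SE 0.101) in susceptible and 0.25 (SE 0.093) in resilient mice. The same list passed with lower values in susceptible hippocampus (median -0.06, adjusted p = 0.000962) and resilient amygdala (-0.08, 0.0307), each with adjusted p = 0.732 with an estimated correlation. Ketamine non-responders had a median of -0.12 against the same susceptible mice (19 of 23 lower), which alone pulls it to the opposite sign. These medians had adjusted p = 2.97e-05, 1.52e-07 and 0.000927, and adjusted p = 0.624, 0.605 and 0.732 with an estimated correlation; no member passed over all genes or over the list alone. Single libraries were not left out for these 2 lists.

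Over the 36 tests of each list, the passes with higher and with lower values were 8 and 9 for immediate early, 9 and 15 for glucocorticoid-responsive, 0 and 2 for stress neuropeptide, 1 and 3 for monoamine, 2 and 6 for glutamate receptor, 3 and 7 for GABA receptor, 1 and 2 for BDNF and mTOR, 7 and 7 for cholesterol and 1 and 5 for circadian genes. They were 11 and 6 for heat shock, 9 and 4 for interferon, 4 and 0 for inflammatory, 17 and 9 for ribosomal, 14 and 8 for oxidative phosphorylation, 5 and 13 for mitochondrial genome and 0 and 5 for histone and DNA methylation genes. Among markers they were 5 and 3 for blood, 13 and 6 for choroid plexus, 6 and 10 for ependyma, 14 and 7 for oligodendrocytes, 6 and 3 for their precursors, 3 and 3 for astrocytes, 14 and 7 for microglia and 5 and 2 for endothelium. The remaining lists had 18 and 3 for mural cells, 2 and 5 for GABA interneurons, 3 and 9 for glutamatergic neurons, 9 and 7 for striatal neurons, 1 and 3 for hippocampus and 9 and 3 for thalamus. With an estimated correlation 0 of the 1080 tests passed.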
